A study of Homo sapiens with 12 samples.

How the data were processed

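The series measured N6-methyladenosine (m6A) on RNA by MeRIP-seq, in which RNA fragments are pulled down with an antibody against m6A and sequenced beside an input library of RNA that was not pulled down. The cells were BT474, an established human breast cancer line with amplified ERBB2, and a derivative resistant to trastuzumab (Herceptin), the antibody against the ERBB2 receptor. There were 12 libraries: 3 pull-down (IP) and 3 input libraries for each line. Groups and replicate numbers came from the sample titles. Peak lists of the 6 IP libraries and 3 tables of the authors' comparison of the lines were used; read counts and signal of the input libraries were not analysed here.

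HISAT2 is named in the submitters' processing notes. The peak caller, the genome build and how replicates entered the comparison are not given in the sources used here. In the peak lists, the fold enrichment of each peak is a ratio with a p-value, both deposited by the authors, per the file headers. Those folds are the authors' and were used to describe, rank or filter peaks within a list. To choose named genes present in a single line, the minimum fold over the lists of that line was ranked. For mitochondrial genes, the folds of different lists and of both lines were also set side by side, without a test. In the comparison tables, the fold is a linear ratio of resistant over sensitive cells and comes with a p-value, both deposited by the authors, per the file headers. The headers do not state whether that p was adjusted for multiple tests. The called regions were checked to be exactly those of the full table with a p below 0.05 and a fold of at least 1.5 or at most 0.667. The full table held few folds near 1: the smallest absolute log2 fold was 0.05, and 165 of 17301 regions lay within 0.1 of 0 on the log2 scale, a limit of 0.1 set for that description. A filter on the fold before deposit would change the median fold, and none is recorded in the headers.

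A peak or region is listed once for each transcript isoform, so 1 stretch of RNA can stand in several rows. Merged regions were therefore also formed, joining rows that share at least 1 exonic base on a strand. The files count positions from 0 and those printed count from 1. No build is named; of 16032 regions whose gene was found by symbol on its chromosome in the GRCh38.p14 gene table, 11.1% lay within the bounds of that gene. That table was used for symbols only: 8110 of 8843 gene names in the files were current symbols and 597 more matched 1 gene by an older symbol. The share of peaks with the m6A sequence motif and an annotation by peak midpoint need a genome and were not computed.

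Numbers of peaks and shares of transcript features, as the authors annotated them, were compared between the 3 resistant and 3 sensitive IP libraries with an exact permutation test, two-sided, whose smallest p with 3 against 3 is 0.1. Nothing in the labels says that replicates came from separate cultures, so permutation p-values measure only the spread between these libraries, which may be technical. Whether the deposited p-values take in that spread is unknown. Fisher p-values count genes or regions and do not measure it. Depth per library is unknown, since the peak lists hold no read totals, and peak numbers depend on depth. Similarity of 2 libraries was the Jaccard index, the bases covered by both divided by the bases covered by either. A region of a line was a merged region with a peak in at least 2 of its 3 libraries. Shares of regions have 95% exact Clopper-Pearson intervals, which cover counting error only. The design allowed for a count model on values per library; the comparison tables hold none, so the authors' own fold and p are reported.

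Before the data were examined, 27 gene lists were fixed. Each was tested with Fisher's exact test, two-sided, for genes with a region called higher or lower, against all genes of the full comparison table, with Benjamini-Hochberg adjustment over 44 tests. Lists with fewer than 5 genes in that table were described without a test. The median log2 fold of each list was placed among 10000 random lists matched on the number of rows per gene. The genes named were also set by a rule fixed before the data were examined: the 10 genes with the largest called fold in each direction, among regions overlapping a peak in at least 2 of 3 libraries of the line in which they were higher; up to 4 genes per list with a called region, by smallest deposited p; the 5 genes per direction with the highest minimum fold enrichment among those with a peak in all 3 libraries of 1 line and none of the other; and METTL3, METTL14, WTAP, FTO, ALKBH5, YTHDF1, YTHDF2, YTHDF3, ERBB2, SLC2A4 and MYC. Genes named outside the rule are said to be so. One result that the rule selects is not reported here.

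The interval and list code was tested on simulated data. All 200 planted genes among 8353 were recovered in the presence comparison, and with no planted difference 21 genes per direction were counted. For the gene lists, on 5553 genes, 0% of simulations without a planted list called a list. Alternatives were stricter peak thresholds (p below 1e-05, fold enrichment of at least 5), equal numbers of top peaks, other overlaps, each library left out, stricter folds and p-values of the comparison, folds divided by their median, merged regions, and leaving out chromosomes 17 and 20. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.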

Results

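m6A was mapped on RNA of trastuzumab-resistant and trastuzumab-sensitive BT474 breast cancer cells, with 3 IP libraries per line. The series asks how m6A differs between the lines. Across the 6 libraries, 8353 genes carried at least 1 m6A peak, and 4670 of them (55.9%) carried one in all 6.

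Resistant cells had more m6A peaks than sensitive cells, on more genes and over more bases. The resistant libraries listed 31868 ± 979 peaks (SD, n = 3) and the sensitive libraries 27738 ± 1554 (SD, n = 3), a difference of 14.9%. These counts hold 1 row per transcript isoform. Merged, the resistant libraries had 11860 ± 401 regions (SD, n = 3) and the sensitive libraries 10476 ± 564 (SD, n = 3), a difference of 13.2%. Genes with a peak numbered 6693 ± 157 (SD, n = 3) in resistant and 6220 ± 213 (SD, n = 3) in sensitive libraries. The lowest resistant library, with 30767 peaks, stood above the highest sensitive library, with 29063. The differences in peaks, merged regions and genes each had p = 0.1 in the exact permutation test. That is the smallest p this design can give, so none of them can pass 0.05. The median fold enrichment within a list lay between 3.39 and 3.67. Read depth per library is unknown.

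**Figure D1:**
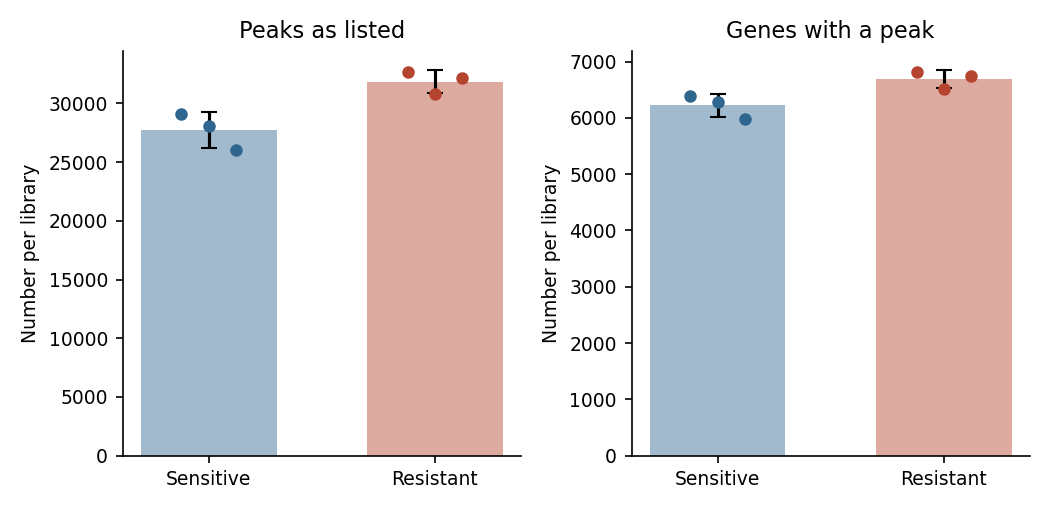
Number of peaks as listed, 1 row per transcript isoform (left), and of genes with a peak (right) per IP library. Bars are means, error bars 1 SD, and points the 3 libraries of each line. All 3 resistant libraries, from 30767 peaks upward, lie above the sensitive libraries, which reach 29063.

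Peaks in both lines lay mainly in coding sequence and 3′ UTRs. Shares are of peaks as listed, once per transcript isoform. Peaks within the coding sequence made up 45.9% ± 0.46 of resistant and 46.1% ± 0.18 of sensitive peaks (SD, n = 3 each). Peaks within the 3′ UTR made up 27.9% ± 0.44 and 28.5% ± 0.26, and those spanning coding sequence and 3′ UTR 18.0% ± 0.39 and 17.6% ± 0.33 (SD, n = 3 each). Peaks within the 5′ UTR were 2.85% ± 0.14 of resistant and 2.69% ± 0.10 of sensitive peaks (SD, n = 3 each). The 6 feature classes differed by at most 0.604 percentage points, for the 3′ UTR, and the ranges of the lines overlapped in every class (exact permutation test, smallest p = 0.2, smallest adjusted p = 0.45; the design cannot pass 0.05). Among peaks with a fold enrichment of at least 5, the 3′ UTR share differed by -1.97 points (exact permutation test, p = 0.2) and the share spanning coding sequence and 3′ UTR by 1.55 points (exact permutation test, p = 0.1). With equal numbers of top peaks per library, the 3′ UTR share was lower in resistant libraries by a difference of -1.62 points and the share spanning coding sequence and 3′ UTR higher by 2.29 points (exact permutation test, p = 0.1 each, the smallest possible).

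Most of the m6A writers, erasers and readers named here, and ERBB2, carried peaks in both lines. Among 5 eraser and reader genes compared, 1 had a called region, and 0 after division by the median fold: HNRNPC, an RNA-binding protein gene, had a 5′ UTR region (chromosome 14, 21730903 to 21731023) at a fold of 1.52 (deposited p = 0.0123) in the authors' deposited table, with a peak in 1 resistant library and no sensitive library. METTL14 and WTAP, parts of the methyltransferase complex, the demethylase ALKBH5, the readers YTHDF1, YTHDF2 and YTHDF3, and ERBB2 and MYC had a peak in all 6 libraries. The demethylase FTO had one in 2 resistant libraries and 1 sensitive library. No peak was listed for the methyltransferase METTL3 or for SLC2A4, the insulin-responsive glucose transporter, in any of the 6 libraries. In the authors' deposited table, the ALKBH5 coding region at chromosome 17, 18087583 to 18087941, had a fold of 1.49 (deposited p = 0.00501), just under the authors' limit of 1.5. The ERBB2 region over the end of the coding sequence and the 3′ UTR (chromosome 17, 37883942 to 37884332) had in the authors' deposited table a fold of 1.14 (deposited p = 1.58e-17). YTHDF1 stood at 1.32, WTAP at 0.924 and the 5 rows of YTHDF2 between 0.817 and 1.65 in the authors' deposited table, none of them called. METTL14, FTO, YTHDF3 and MYC have no region in that table.

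Some genes carried m6A peaks in a single line. A peak in all 3 resistant and no sensitive library was found for 149 genes, and the opposite for 70 genes. Among the resistant-only genes, those with the highest fold enrichments were FOXO1, a transcription factor held in check by AKT, the potassium channel gene KCNK5, the vacuolar proton pump subunit ATP6V0A2, RAB36 and RTCA. The FOXO1 peak with the smallest p lay in the coding sequence (chromosome 13, 41134160 to 41134369). The highest fold enrichments of any FOXO1 peak in the 3 resistant lists were 15.2, 16.7 and 19.7. For KCNK5, the peak with the smallest p lay at the end of the coding sequence (chromosome 6, 39158656 to 39158835), and the highest fold enrichments were 19.3, 18.1 and 16.2. Such values need not belong to the peak at the printed position. Some recurred between genes: resistant replicate 3 gave 16.2 for KCNK5, RAB36 and ATP6V0A2. The reads behind such values were not analysed here. Sensitive-only genes included the kinase gene NUAK2, the PCNA-binding factor KIAA0101, the mucin gene MUC19, LRG1 and BTN3A3. For NUAK2, the peak with the smallest p lay in the 3′ UTR (chromosome 1, 205271605 to 205271754). Its highest fold enrichments in the 3 sensitive lists, over all peaks of the gene, were 21.2, 22.2 and 21.6. For LRG1, that peak lay in the 3′ UTR (chromosome 19, 4537522 to 4537909), and the highest values were 28.3, 26.6 and 20.3. The amount of RNA of these genes in each line was not analysed here.

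Of the 149 resistant-only genes, 117 had a region in the authors' deposited table and 39 a region called higher. Of the 70 sensitive-only genes, 40 had a region there and 7 a region called lower. Among the 10 genes named, KCNK5, ATP6V0A2 and RTCA had a region called higher and MUC19 a region called lower; NUAK2 and BTN3A3 were compared without a call, and FOXO1, RAB36, KIAA0101 and LRG1 had no region there. The excess on the resistant side turned with the length of the lists: with the same number of top peaks per library, 101 genes were resistant-only and 113 sensitive-only. At a peak p below 1e-05, none of these 10 named genes still had a peak in all 3 libraries of its line. The median p of a list lay between 1.86e-07 and 4.68e-07. A high fold enrichment of these genes thus did not go with a small p in every library of the line.

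At the level of regions, most m6A sites were shared. Resistant cells had 10318 regions found in at least 2 of 3 libraries, and 24.4% of them (95% interval 23.6 to 25.2) overlapped no such region of sensitive cells. Sensitive cells had 9093, and 12.3% of them (95% interval 11.6 to 13.0) overlapped none of the resistant cells. Libraries of a line were more alike than libraries of different lines: the Jaccard index was 0.638 to 0.646 within resistant, 0.614 to 0.616 within sensitive and 0.562 to 0.594 between the lines (exact permutation test, p = 0.1, the smallest possible). With equal numbers of top peaks the shares without overlap came to 18.6% and 16.8%. Leaving out any 1 resistant library put the sensitive share above the resistant one, at 20.2% against 17.04% without resistant replicate 1, 18.9% against 18.4% without replicate 2 and 20.05% against 17.1% without replicate 3; a region then had to be in both remaining libraries of that line.

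Regions that differed between the lines were mostly higher in resistant cells. The authors' deposited table compares 17301 regions of 5553 genes and calls 1709 higher and 302 lower in resistant cells, on 790 and 153 genes, 13 of them in both sets. A region is listed there once for each transcript isoform; merged, 850 were called higher and 154 lower. Thus 85.0% of the called regions were higher. The whole table leaned the same way, with a median fold of 1.25 (median log2 fold 0.32) and 75.04% of regions above 1. After division of every fold by that median, a scaling chosen after seeing the data, 492 regions were called higher and 823 lower, so that 37.4% were higher. Directions below are those of the deposited folds, and that shift of 0.32 on the log2 scale applies to each of them.

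**Figure D2:**
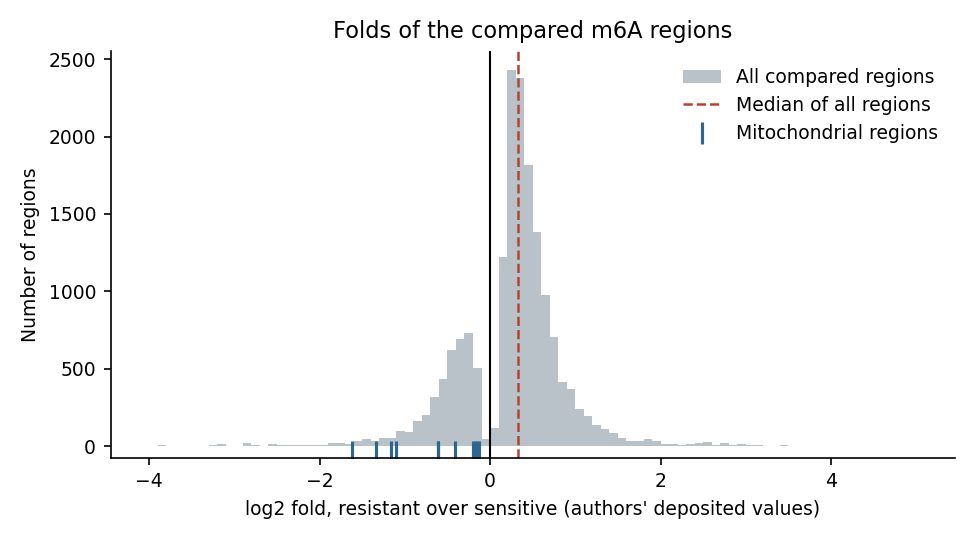
Histogram of the log2 fold of resistant over sensitive cells for the 17301 regions of the authors' deposited table, in bins of 0.1; the dashed line is the median, 0.32, and the ticks under the bars are the 11 mitochondrial regions. Most regions lie to the right of 0, few lie close to 0, and all 11 mitochondrial regions lie to the left.

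Among called regions overlapping a peak in at least 2 of 3 resistant libraries, the largest folds lay on PDGFB, CDK2AP1, FGD4, MAN2B2 and ESPN. In the authors' deposited table, PDGFB, which encodes a platelet-derived growth factor chain, had the largest fold of this set, 6.73, for a 5′ UTR region (chromosome 22, 39640039 to 39640218; deposited p = 0.00447), but the median fold of its 3 listed rows was 0.801; merged, its 2 regions had a median of 2.30. TGFB1, which encodes transforming growth factor beta, had in the authors' deposited table a fold of 3.32 over the end of its coding sequence and the 3′ UTR (chromosome 19, 41836794 to 41837061; deposited p = 0.0468), with a peak in 3 resistant libraries and no sensitive library. CDK2AP1, a negative regulator of the cell cycle kinase CDK2, had in the authors' deposited table a fold of 4.17 in the 5′ UTR (chromosome 12, 123756215 to 123756569; deposited p = 0.000417). The remaining genes of this set in the authors' deposited table were FGD4 (3.97), MAN2B2 (3.89), the actin-bundling gene ESPN (3.73), NAPEPLD (3.43), TPRN (3.36), QSER1 (3.29) and CNTD2 (3.10). MAN2B2 also had 1 region called lower. FGD4 was called in 1 of its 6 rows, with a median fold of 1.45 over the rows and 2.40 over its 2 merged regions. The FGD4 and ESPN regions each overlapped a peak in 2 resistant and 2 sensitive libraries, and the TPRN region in 2 and 1. Those of the other genes of this set overlapped none in sensitive libraries. With Benjamini-Hochberg adjustment over all regions, chosen after seeing the data, 6 of these 10 genes stayed past the threshold, and TGFB1, NAPEPLD, QSER1 and CNTD2 did not.

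Among called regions overlapping a peak in at least 2 of 3 sensitive libraries, the folds farthest below 1 lay on MUC19, ABHD11, NLRX1, MESDC2 and PHF14. In the authors' deposited table, MUC19 had a fold of 0.104 in the 3′ UTR (chromosome 12, 40879379 to 40880458; deposited p = 0.00214), with a peak in 3 sensitive libraries and no resistant library. ABHD11 had a fold of 0.138 for 1 merged region and NLRX1, a mitochondrial regulator of innate immunity, 0.332. Of the 5 rows of NLRX1, in 1 merged region, 2 were called lower, and the median fold over the rows was 0.718. IL6ST, the signalling receptor subunit shared by interleukin 6 family cytokines, had in the authors' deposited table a fold of 0.454 (chromosome 5, 55236910 to 55237090; deposited p = 0.0479), with 1 of its 2 merged regions called lower and a median fold of 0.894 over both. The other genes of this set in the authors' deposited table were MESDC2 (0.379), PHF14 (0.409), RGL1 (0.426), TNNT1 (0.441), ZNF763 (0.451) and MBP (0.460); over both of its regions, the median fold of MESDC2 was 1.14. With the same adjustment, 4 of these 10 genes stayed past the threshold, and ABHD11, NLRX1, PHF14, RGL1, IL6ST and MBP did not. The ABHD11 region overlapped a peak in 2 resistant and 2 sensitive libraries, and the MBP region in 3 and 3. Those of MESDC2, RGL1, ZNF763 and IL6ST overlapped peaks in both lines, in more sensitive than resistant libraries. Those of NLRX1, PHF14 and TNNT1, like that of MUC19, overlapped none in resistant libraries.

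**Figure D3:**
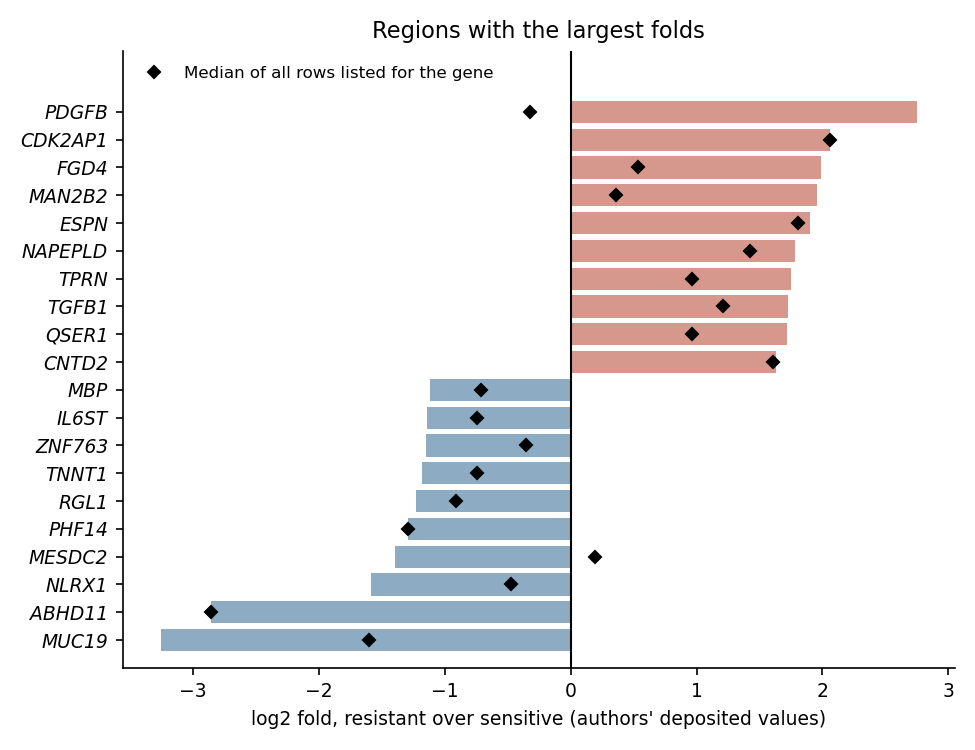
Bars give the log2 fold of resistant over sensitive cells for the called region with the largest fold of each of 10 genes per direction in the authors' deposited table, among regions with a peak in at least 2 of 3 libraries of the line in which they were higher; diamonds give the median over all rows listed for the gene, 1 per transcript isoform. PDGFB and MESDC2 have a median on the other side of 0 from their bar; over merged regions this held for MESDC2.

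Of 16 genes of PI3K, AKT and mTOR signalling, a pathway downstream of ERBB2, 5 had a region called higher, 0 lower and 11 none. Over all 5550 genes compared, counted after older symbols were replaced by current ones, 14.2% had a region called higher, and 153 genes had one called lower. In the authors' deposited table, TSC2, an inhibitor of mTOR complex 1, had its 1 merged region, listed for 8 isoforms, called higher, with a fold of 1.89 at chromosome 16, 2138515 to 2138692 (deposited p = 0.00331). In the authors' deposited table, AKT1 stood at 1.51 (deposited p = 0.00102), the regulatory subunit gene PIK3R2 at 1.51 (deposited p = 2.57e-06) and FOXO3 at 1.52 (deposited p = 0.0174). AKT1 was called in 2 of its 6 rows, with a median fold of 1.497 over the rows and 1.67 over its 2 merged regions. FOXO3 was called in 1 of its 4 rows, with medians of 1.37 and 1.39. The list did not pass (Fisher's exact test, p = 0.0653, adjusted p = 0.719). With Benjamini-Hochberg adjustment of the deposited p, 3 of these genes had a called region over all regions and 4 adjusted over the list alone. After division of the folds by their median, 2 genes of the list were called higher.

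ERBB receptor genes and their adaptors showed little difference. Of 11 compared, 0 had a region called higher and 1, the adaptor GAB2, a region called lower, with a fold of 0.500 (deposited p = 0.0490) in the authors' deposited table and no overlapping peak in any library. Among 15 neighbours of ERBB2 in its amplified segment, PIP4K2B had a region at 1.79 (deposited p = 1.58e-12), while MLLT6 (0.633) and STARD3 (0.590) each had 1 region called lower in the authors' deposited table. With adjustment over all regions, GAB2, MLLT6 and STARD3 were not past the threshold: 0 ERBB genes were left over all regions and 0 adjusted over the list alone, and 1 and 2 of the amplicon genes. With folds divided by their median, 0 amplicon genes were called higher and 2 lower. The lower direction of that list had p = 0.0627 and adjusted p = 0.719 in Fisher's exact test. The median over the 9 rows of MLLT6 was 1.09, and over its 7 merged regions 0.865.

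A list of zinc finger genes, fixed together with the KRAB corepressor TRIM28, had the smallest unadjusted p of the lists. Of 25 compared, 8 had a region called higher and 0 lower: TRIM28 and ZNF202, ZNF263, ZNF282, ZNF462, ZNF526, ZNF574 and ZNF687. Of these, ZNF462, ZNF526, ZNF574 and ZNF687 are not known to carry a KRAB domain. ZNF202, ZNF263, ZNF462 and ZNF574 are named outside the rule. TRIM28 had its 1 merged region, in the 3′ UTR, called higher, with a fold of 1.70 (chromosome 19, 59061940 to 59062089; deposited p = 6.31e-12) in the authors' deposited table. ZNF282 stood at 1.56, ZNF526 at 1.78 and ZNF687 at 1.61 in the authors' deposited table. The list had p = 0.0188 in Fisher's exact test and adjusted p = 0.719, so it did not pass. Over all genes whose symbol starts with ZNF, a set chosen after seeing the data, there was no excess among genes called higher (4.56% against 4.64% of the others, Fisher's exact test, p = 1), and among genes called lower the share was 7.84% against 4.54% (Fisher's exact test, p = 0.0743). Of the called genes, 4 kept a region past the threshold with adjustment over all regions and 2 adjusted over the list alone. After division of the folds by their median, 1 gene was called higher and 1 lower.

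Of 33 chromatin regulators compared, 7 had a region called higher and 0 lower, among them ARID1A and ARID1B, subunits of the SWI/SNF remodelling complex, and the histone methyltransferases KMT2D and KMT2B. In the authors' deposited table the ARID1A coding region at chromosome 1, 27057691 to 27087365, had a fold of 1.80 (deposited p = 1.23e-08), KMT2D 1.51, KMT2B 1.58 and ARID1B 2.10, although the median over the 9 rows of ARID1B was 0.853, and over its 2 merged regions 1.33. The list had p = 0.312 in Fisher's exact test; adjustment over all regions and adjusted over the list alone both left 5 genes. After division by the median fold, 3 genes were called higher.

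Mesenchymal and basal genes with a compared region were few. Of 6, 3 had a region called higher: TGFB1, its receptor gene TGFBR1 (1.51, deposited p = 0.0105) and the integrin gene ITGB4 (1.80, deposited p = 0.0107), in the authors' deposited table. TGFBR1 was called in 1 of its 3 rows, with a median fold of 1.49 over them. This list had p = 0.0411 and adjusted p = 0.719 in Fisher's exact test, with 2 genes left over all regions and 0 adjusted over the list alone. After division by the median fold, 1 gene was called higher.

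In autophagy and lysosome genes, 4 of 14 had a region called higher. The authors' deposited table gives ATG12 2.25, the lysosomal protease gene CTSD 1.66 (deposited p = 4.90e-08), ATG2A 1.51 and ULK1 1.52. ATG2A was called in 1 of its 6 rows, with a median fold of 1.31 over them. Among Hippo pathway genes, 2 of 14 were called higher, TEAD3 at 2.36 (deposited p = 7.08e-08) and the kinase gene STK4 at 1.64, in the authors' deposited table. Of 20 Wnt, Notch and stemness genes, LRP5 (1.75) and TCF7L2 (2.60) were called higher in the authors' deposited table, TCF7L2 in 1 of its 2 merged regions. Of 6 further tyrosine kinase genes, YES1 (2.23, deposited p = 3.55e-10) and SRC (1.67) were called higher in the authors' deposited table. After division by the median fold, 1 autophagy, 1 Hippo and 1 Wnt, Notch and stemness gene were called higher and 1 of each lower, and 1 further tyrosine kinase gene was called higher; CTSD, ATG2A, ULK1, STK4, LRP5 and SRC were no longer called. Adjusted over all regions and adjusted over the list alone alike, 3, 2, 2 and 1 genes of these lists were left.

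Of 13 cell cycle genes compared, RB1 and CDKN2C had called regions. RB1, the retinoblastoma tumour suppressor, had a fold of 2.27 (chromosome 13, 48878030 to 48881529; deposited p = 0.00661) in the authors' deposited table, with a peak in 3 resistant libraries and no sensitive library. CDKN2C had 1 merged region called higher, at up to 2.04, and 1 called lower in the authors' deposited table, with a median fold of 0.649 over its listed rows and 1.13 over the merged regions. Of 15 apoptosis genes, MCL1 (1.65) was called higher in the authors' deposited table, and of 11 DNA damage response genes, MDM2 (1.502) and MDM4 (1.64). MDM2 was called in 2 of its 5 rows, with a median fold of 1.48 over them. The authors' deposited table calls 1 of 15 RAS and MAPK genes higher, RPS6KA1 at 1.58. That call was for 1 of its 10 rows, with a median fold of 1.30 over the rows and 1.09 over its 2 merged regions. In the authors' deposited table, 1 of 11 genes of the unfolded protein response was called higher, CHAC1 at 1.61. Of 5 hypoxia genes, VHL (1.87) was called higher there, and of 7 NF-κB genes, RELA (1.71, in 1 of its 2 merged regions) and TNFAIP2 (2.30, in its 1 merged region) in the authors' deposited table. With folds divided by their median, 0 apoptosis, DNA damage response, RAS and MAPK, unfolded protein response or hypoxia genes were called higher, and 1 apoptosis, 1 RAS and MAPK and 1 hypoxia gene lower; 1 NF-κB gene was called higher, and 2 cell cycle genes in each direction. With adjustment over all regions, MCL1, MDM4, RPS6KA1 and TNFAIP2 were not past the threshold. Adjusted over the list alone, 0 apoptosis, 0 RAS and MAPK, 2 DNA damage response and 2 cell cycle genes were left, and 1 gene of each of the other lists.

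Metabolic and drug efflux genes were mostly without a called region. SREBF1, the master regulator of lipid synthesis, had its 1 merged region called higher, with a fold of 1.66 (chromosome 17, 17722979 to 17740205; deposited p = 7.94e-13) in the authors' deposited table, and MVD, an enzyme of sterol synthesis, had a fold of 0.536. None of 7 glycolysis and glucose uptake genes, 6 ABC transporters, 3 m6A writers or 3 interferon and antigen presentation genes had a called region with the deposited folds. Division by the median fold left 1 glycolysis gene, 1 ABC transporter and 1 m6A writer called lower, and 1 lipid gene higher and 2 lower. Marker lists of fibroblasts, leukocytes and endothelium had 0 genes in the authors' deposited table, and 1 fibroblast marker had a peak in any library.

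Of the 44 list tests, 0 passed an adjusted p of 0.05 and 2 had an unadjusted p under 0.05 (Fisher's exact test). In the comparison of each list's median log2 fold with random lists, 0 lists passed after Benjamini-Hochberg adjustment. The highest were hypoxia genes (median 0.86 over 5 genes, percentile 98.96), NF-κB genes (0.71 over 7 genes, percentile 98.38) and mesenchymal and basal genes (0.60 over 6 genes, percentile 96.48). With regions that overlap a peak in at least 2 of 6 libraries, 4 hypoxia and 3 NF-κB genes were left, too few to test, and mesenchymal and basal genes stood at percentile 97.5.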

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

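Division by the median fold, merged regions, adjustment of the deposited p, medians over a gene's regions and leaving out mitochondrial regions (1709 called higher and 296 lower) were chosen after seeing the data. Resistant libraries had more peaks under every alternative run, by 1.11 to 1.25 times, and 1.08 times as many genes with a peak, and the Jaccard difference kept its sign. The replicate numbers showed no pairing in the presence of peak regions: same-numbered libraries had correlations of -0.01, -0.001 and -0.009. Whether same-numbered libraries were prepared together is not stated in the labels. A replicate block gave a ratio of 1.15 (exact sign-flip p = 0.25, the smallest possible). Under the block the presence counts stay 149 and 70 by construction, and the mean shares of regions without overlap were 31.8% and 20.6%. Counted as merged regions in place of genes, 373 regions were resistant-only and 122 sensitive-only. Sensitive-only genes numbered 44 at a fold enrichment of at least 5 and 113 with equal numbers of top peaks. Leaving out 1 library gave 219 to 264 resistant-only and 97 to 116 sensitive-only genes. These passed 1.5 times the full count for resistant-only genes without resistant replicates 1 (228) and 2 (234) and sensitive replicates 1 (264) and 2 (247), and for sensitive-only genes without resistant replicate 1 (115) and sensitive replicates 2 (109) and 3 (116); fewer libraries then had to agree. Shares without overlap in resistant and sensitive cells were 37.6% and 22.3% at a fold enrichment of at least 5, 33.1% and 24.1% at a reciprocal overlap of 50%, 18.6% and 16.8% with equal numbers of top peaks, 17.04% to 35.9% and 7.25% to 20.2% with 1 library left out (7.25% and 7.92% for sensitive without sensitive replicates 1 and 2, and 20.2%, 18.9% and 20.05% without resistant replicates 1, 2 and 3), 25.6% for resistant in 3 of 3 libraries, and 11.3% for sensitive at p below 1e-05. Feature differences changed sign with equal numbers of top peaks for the 5′ UTR (-0.191 points) and for peaks over all parts (0.0384 points), and for coding sequence with 1 library left out (-0.456 to 0.00594 points); the cause was not tested. Regions called higher and lower numbered 40 and 11 at a fold of at least 4, 198 and 10 at p below 1e-06, 492 and 823 after division by the median, 850 and 154 as merged regions and 1132 and 134 with adjusted p. After division by the median, 33 of the folds chosen by the rule for named genes stayed past the limit of 1.5 and 29 did not; with adjusted p, 41 stayed past the threshold and 21 did not. By the median over a gene's listed rows, 41 of these folds stayed past the limit of 1.5 and 16 kept their side without passing it. The other 5 changed side: PDGFB (0.801), MESDC2 (1.14), MLLT6 (1.09), CDKN2C (0.649) and ARID1B (0.853). Over merged regions, 41 stayed past the limit, 20 kept their side without passing it and 1, MESDC2 (1.14), changed side. No list test passed under any alternative run. A midpoint annotation, and count models, pseudocounts, block and left-out libraries for the deposited comparison, were not run, since no values per library were used. Depth is unknown, so its effect on peak numbers cannot be measured here.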

Other observations

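The tests below of other splits of the libraries, transcript position, chromosome 19, a constant offset and repeated transcripts were chosen after the results were seen; those of IP separation and of non-specific pull-down were set before their results were seen.

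Regions called higher lay more often at the start of transcripts and less often within the coding sequence, and neither is shown to be particular to that direction. Of 850 merged regions called higher in the authors' deposited table, 21.8% touched a 5′ UTR, against 14.2% of the other 6834 (Fisher's exact test, odds ratio 1.68, adjusted p = 4.52e-07 over 18 such tests). CDK2AP1, PDGFB, RB1 and SREBF1 are examples. Among regions listed in a single row the shares were 19.8% and 14.5% (Fisher's exact test, adjusted p = 0.0366), and for regions called lower 24.2% and 14.8% (Fisher's exact test, adjusted p = 0.107). Over all merged regions called lower, 17.5% against 15.0% touched a 5′ UTR (Fisher's exact test, adjusted p = 0.594). Regions within the coding sequence were rarer among those called higher, 22.2% against 27.9% (Fisher's exact test, adjusted p = 0.00197), and also among those called lower, 18.2% against 27.5% (Fisher's exact test, adjusted p = 0.0319). Genes on chromosome 19 made up 12.7% of genes with a region called higher and 8.08% of the others (Fisher's exact test, odds ratio 1.65, adjusted p = 0.000333). Chromosome 19 genes whose symbol does not start with ZNF made up 10.6% against 5.77% (Fisher's exact test, adjusted p = 1.35e-05). Among genes called lower, chromosome 19 held 10.5% against 8.69% (Fisher's exact test, adjusted p = 0.645), and 4.58% against 6.52% without the ZNF symbols (Fisher's exact test, adjusted p = 0.609). Neighbouring regions and genes are not independent, and GC content was not analysed here.

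The largest called folds lay on regions without a peak in any of the 6 lists. BOD1L1, at 30.1 (chromosome 4, 13629197 to 13629317), and ZNF225, at 0.0836 (chromosome 19, 44619962 to 44622450), had the highest and lowest fold among called regions of the authors' deposited table; both were chosen after their values were seen. The other regions of BOD1L1 stood at 1.26 and 1.17.

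Genes with a peak in all libraries of 1 line and none of the other numbered 219 in the real grouping and at most 66 in any other of the 10 splits of the 6 libraries; 1 split, the real one, reached that number. With 10 splits, a share under 0.05 cannot be reached.

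The deposited comparison leaned towards resistant cells. Repeated listing of transcripts is argued against, since 84.7% of called merged regions were higher when each was counted once. A sharper separation of IP from input in the resistant libraries may contribute: log2 fold rose with the within-library rank of fold enrichment across 2514 merged regions with a peak in all 6 libraries (Spearman rho 0.149, bootstrap interval 0.108 to 0.188), between the bounds of 0.1 and 0.2 that would have decided. An offset shared by all nuclear regions, from pull-down efficiency or scaling, and a real gain of m6A in resistant cells cannot be told apart. Division by the median removes a shared shift whatever its cause. The share called higher was then 37.4%, below the range set for a constant offset after the results were seen. That share cannot separate an offset from a real gain.

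Mitochondrial transcripts went against this lean: all 11 regions on the mitochondrial genome had folds below 1 in the authors' deposited table, with 6 called lower, among them MT-ND4L (0.325), MT-ND6 (0.395), MT-ND5 (0.448) and MT-ND3 (0.467), subunits of respiratory complex I. The mitochondrial genes are named outside the rule. In the authors' fold enrichment, sensitive replicate 1 was the highest of the 3 sensitive lists for 1 of the 6 called lower. Replicate 2 was the highest for the other 5, as in MT-ND4 (152, 170 and 61.2, resistant lists at most 5.77) and MT-CYB (64.9, 74.0 and 35.9, resistant lists at most 4.09). Among the 6, the lines overlapped only for MT-ND5 (26.6, 14 and 8.27, resistant lists 18.2, 12.2 and 10). Replicate 1 stood apart from the other sensitive lists for MT-ND2 (1580, 23.5 and 19.3) and MT-ND1 (121, 5.67 and 4.95). It also did so for MT-CO1 (31.9, 2.01 and 2.3) and MT-CO3 (23.9, 1.55 and 1.62), where the other sensitive lists lay below all resistant lists. None of those genes had a called region. The median log2 fold of the 11 regions, -0.61, lay below the lower quartile of nuclear regions, 0.07. As an explanation, a constant offset shared with nuclear regions would not by itself give that gap. The rule was set after these folds were seen and uses the same 11 values, so it restates the pattern and is no separate test. The 11 regions lie on 1 genome and are not independent. Another explanation is a general change in pull-down of RNAs covered almost end to end by a peak. It predicted a median log2 fold below 0 for 148 nuclear merged regions covering at least 80% of their transcript. Their median was 0.22 (bootstrap interval 0.17 to 0.24), above 0 but below the median of all nuclear regions as listed, 0.32. The shift shared by the whole table was not removed, so this test cannot decide. A difference in the amount or handling of mitochondrial RNA and a difference between the lines stay open and were not tested.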
